A study of Mus musculus with 6 samples.

How the data were processed

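RNA from Hepa1-6 cells was measured by sequencing in 6 samples, 3 titled shNC, taken as control, and 3 titled shZfp207, taken as Zfp207 knockdown by short hairpin. The titles do not give the number of hairpins, so other effects of a hairpin cannot be told apart from loss of Zfp207. The labels' protocols give culture, Trizol extraction of total RNA and library preparation by standard Illumina procedures. They also tag the samples as tumor although the growth protocol describes cultured cells, and the samples were treated as a cell line. Whether the replicates came from separate cultures is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

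The deposited count table gives whole-number read counts per gene for each sample, with no normalization, for 34718 genes. The authors also deposited FPKM values for the same genes. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the build mm10, without stating the role of each, and the annotation, the strand setting and any filter are not given in the sources used here. Counts of a gene and of a gene overlapping it on the opposite strand may therefore be mixed. The FPKM values were checked against the counts: over 9768 genes with many counts, the gene length implied by the ratio of the deposited count and FPKM values was the same in all libraries within 0.023%, so the FPKM values carry no normalization between samples beyond the library total. All per-sample columns of the tables were used.

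Gene identifiers were matched to GENCODE mouse release M21, which uses the GRCm38 assembly that mm10 denotes. Of the identifiers 98.8% were found there, 80.9% with the same start and end. Coordinates in the text are those of the deposited tables, and strand, exonic overlap, exonic length and GC content come from the annotation. Overlap was summed over the overlapping genes and capped at the exonic length. A stretch shared with several genes thus counts more than once, and the percentages are upper bounds.

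Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on the 2 groups, which left 11975 genes, while 16424 had no count in any library. Libraries were scaled by TMM, a quasi-likelihood model was fitted with the group as its only term to all 6 libraries, and two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes tested. The threshold was an adjusted p below 0.05. A second count took genes that also changed at least 2-fold. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. Group means ± SD are TMM-scaled CPM over 3 libraries, and values per library are counts per 1000000 counts of that library (CPM). Counting intervals are exact at 95%.

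The design, the tests, 27 gene lists and the rule for named genes were fixed before the data were examined. The rule names Zfp207, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 2 CPM and no overlap between the groups, all measured kynurenine pathway genes, up to 4 members with the smallest p from each other list (the 2 most abundant where none passes), and the 5 genes with the smallest p. Predicted gene models and pseudogenes are left out of the parts for largest changes and smallest p. Genes named outside the rule are marked as such, and some genes that the rule selects or a figure would show are not reported here. The 23 lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera compares a list with all other genes. It was repeated with an estimated correlation, which also cuts the degrees of freedom to the few residual ones of the fit. A call lost there need not be lost through correlation. As an alternative fry was run, which asks only whether the genes of a list move on balance one way.

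The procedure was tested on simulated data, with counts drawn for the 11975 tested genes from the means, library sizes and dispersions of these samples and 200 genes changed. It recovered 6% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 87.9% of those changed 4-fold, with 4.9% false calls. A second draw from the same means, library sizes and dispersions shifted only a list of 25 genes. There camera called that list, and 2 of 100 random lists of other genes fell below an unadjusted 0.05. Genes were drawn independently and no simulated library was made to stand apart. The 200 genes changed in the first draw were also far fewer than the 2466 called in these samples. The adjusted threshold was thus stricter in unadjusted p there. These rates therefore need not hold where many genes change, where genes of a list move together or where 1 library deviates, as in these samples.

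The alternatives were RLE and upper-quartile scaling, no filter beyond 1 count, a filter of at least 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, a replicate block, limma with a trend on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 1 or without a filter, an adjusted p below 0.01, and each library left out in turn. After the data were examined 4 more were added: the log2 mitochondrial share of each library as a covariate, mitochondrial genes left out, smooth offsets in exonic length and GC content, and an estimated correlation in the fit without control replicate 1. Fold changes on log2(FPKM + 1) are understated for low genes. Pairs of libraries were compared by a chi-square statistic over genes with a summed count of at least 20, to look for libraries sequenced or deposited more than once. Annotation and figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.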

Results

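The study measured messenger RNA by sequencing in Hepa1-6, a mouse hepatoma cell line that grows in culture, after knockdown of Zfp207 by short hairpin. Zfp207 is the mouse counterpart of human ZNF207, a zinc finger protein also known as BuGZ that binds the spindle checkpoint protein BUB3. There were 6 libraries, 3 from control cells and 3 from knockdown cells. The gene counts summed to 11933736, 14591630 and 16248346 in control replicates 1 to 3 and to 15236957, 15074588 and 14629661 in knockdown replicates 1 to 3. A ceiling of 3 counts, the most that an observed count of 0 allows, corresponded to 0.251, 0.206 and 0.185 CPM (counts per 1000000 counts) in the control libraries and to 0.197, 0.199 and 0.205 CPM in the knockdown libraries, covering counting error only.

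Zfp207 itself was lower in every knockdown library than in every control library. It had 141.4, 198 and 216.8 CPM in control replicates 1 to 3 and 48, 48.1 and 46.8 CPM in the knockdown replicates. On the scale used for testing the means were 184.9 ± 40 CPM in control cells and 47.9 ± 0.614 CPM in knockdown cells (SD, n = 3 each), so that 0.259 of the control level remained. The log2 fold change was -1.95 (SE 0.17, edgeR adjusted p = 0.00236), and it stayed between -2.11 and -1.82 with each library left out. The gene (ENSMUSG00000017421) lies on the plus strand of chromosome 11 from 80383279 to 80405733 in mm10, and none of its exonic sequence overlaps another annotated gene. A two-sided exact permutation test of the 3 against 3 CPM values gave p = 0.1, the smallest value this design can reach.

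**Figure D1:**
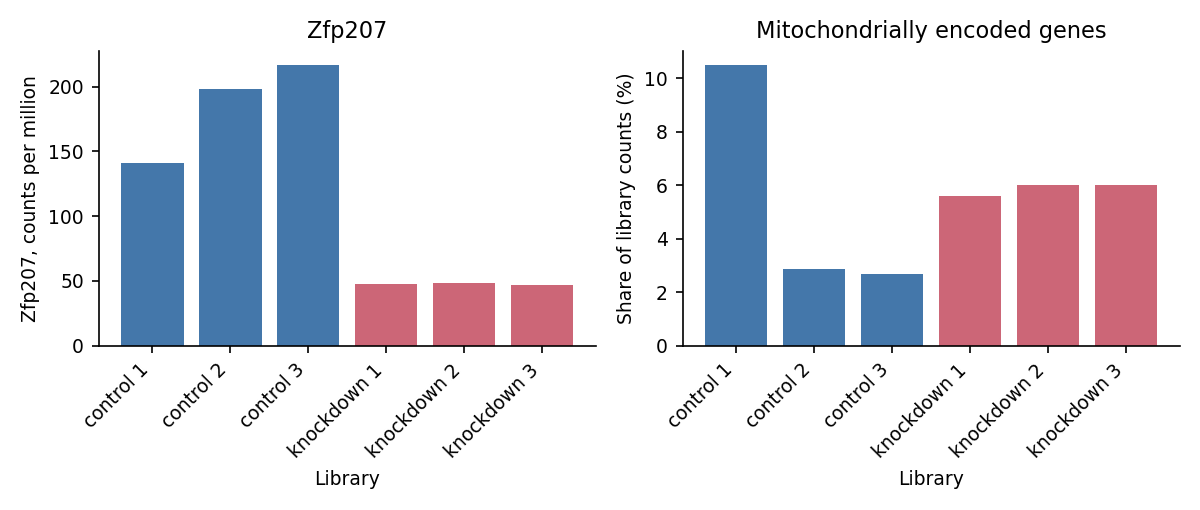
Zfp207 in CPM (left) and the share of library counts in mitochondrially encoded genes in percent (right), by library, with control libraries in blue and knockdown libraries in red. Zfp207 lay between 141.4 and 216.8 CPM in the control libraries and between 46.8 and 48.1 CPM in the knockdown libraries, while the mitochondrial share was 10.51% in control replicate 1, 2.89% and 2.67% in the other control libraries and 5.6% to 6% in the knockdown libraries.

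Control replicate 1 stood apart from the other control libraries. Mitochondrially encoded genes took 10.51% of its counts against 2.89% and 2.67% in control replicates 2 and 3, and 5.6%, 6% and 6% in knockdown replicates 1 to 3. The nuclear long noncoding RNA Malat1 had 330.8 CPM in control replicate 1, 30.8 and 30 CPM in control replicates 2 and 3, and 104.3 to 129.5 CPM in the knockdown libraries. Xist, Neat1, Kcnq1ot1 and Firre had the same order, with Xist at 507.8 CPM in control replicate 1, 81.6 and 72.3 CPM in the other controls and 327.4 to 351.4 CPM in knockdown cells. These 5 noncoding RNAs lie outside the naming rule and were chosen after the data were examined. The log2 CPM of control replicate 1 correlated across genes at r = 0.95 with each of the other controls, against 0.989 between those 2 and 0.99 to 0.991 among the knockdown libraries, where genes are not independent replicates. No pair of libraries agreed within counting noise, so each was counted as a separate sample.

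Knockdown cells differed from control cells at 2466 of the 11975 genes tested, of which 1188 were higher and 1278 lower. Of these, 702 changed at least 2-fold, 365 upward and 337 downward. All 3 libraries of a group lay above all 3 of the other at 5352 genes (44.7%), where 10% would be reached by chance. Among the largest rises, Ces2g, a carboxylesterase gene on chromosome 8, went from 1.43 ± 0.0712 to 32.6 ± 1.34 CPM (log2 fold change 4.51, SE 0.131, edgeR adjusted p = 9.13e-05), and it also had the smallest p of the named genes. Cdh16, which encodes kidney cadherin, rose by 3.67 on the log2 scale, Tgfbi, a secreted matrix protein gene, by 3.72, and Abcb4, the phospholipid exporter of the bile canaliculus, by 3.54. The organic anion transporter gene Slco1a4 had 2 counts over the control libraries and 200 over the knockdown libraries, a ratio of 95.2 after scaling by library totals (95% exact counting interval 26 to 791, counting error only). Its 2 control counts were both in control replicate 1, so that without this library the control count was 0 and the ratio has no upper bound. Krtap1-5, Adgrf5, Mal and C1s2 were also among the largest rises, with log2 fold changes of 4.61, 3.62, 3.03 and 2.98. Ces2g and C1s2 have close paralogs with which reads could be shared.

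Among the largest falls, Cyfip2, which encodes a subunit of the actin-regulating WAVE complex, went from 15.2 ± 2.47 to 0.986 ± 0.18 CPM (log2 fold change -3.94, SE 0.226, edgeR adjusted p = 0.0014). Chchd10, a mitochondrial intermembrane space protein gene, had a log2 fold change of -3.60, the myelin protein gene Pmp22 one of -3.28, the peptidylarginine deiminase gene Padi4 one of -3.23, and Chad, which encodes the cartilage protein chondroadherin, one of -3.10. For Chchd10, up to 11.4% of the exonic sequence overlaps a gene on the opposite strand. Fndc4, Crisp1, Ramp3 and Rasl10b followed with log2 fold changes of -3.03, -2.93, -2.75 and -2.73. Pcdhga1 had the most negative value, -5.34 (SE 1.29, edgeR adjusted p = 0.0315). Its annotated exons overlap those of other protocadherin gamma genes, to an extent that the summed overlap does not resolve, and its level is uncertain. The genes with the smallest p also included the metallothionein gene Mt1 (-1.75), Cntnap5a (-2.55), the Hippo pathway kinase gene Stk4 (1.58) and the galactosyltransferase gene B4galt5 (1.53), each with edgeR adjusted p = 0.00113. Of the largest rises and falls named here, all but Pcdhga1 kept their direction and edgeR call with each library left out.

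These counts depended on which libraries entered the fit. Leaving out control replicate 1 raised the count to 6313 of 12108 genes tested, 3158 higher and 3155 lower, and the count at least 2-fold to 1092. The 6313 included all 2466 with the same sign. Counts of list members in that fit are to be read against this share, and those with all libraries against 2466 of 11975. Leaving out control replicate 2 or 3 gave 1529 or 1260 genes, and leaving out knockdown replicate 1, 2 or 3 gave 719, 596 or 534. The 2-fold count was 382, 338 and 323 without knockdown replicates 1, 2 and 3. Of the 95 genes named here that passed the threshold, 45 kept the call with each of the 6 libraries left out.

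The title of the series names kynurenine metabolism, so the enzymes that convert tryptophan along the kynurenine pathway were examined as a list whose theme comes from the study itself. Of 13 enzymes, 6 had enough counts to test, and 1 was lower and 0 higher in knockdown cells. Ccbl2, also called Kyat3, a kynurenine aminotransferase gene (chromosome 3, 142701051 to 142746870), fell from 139.1 ± 11.9 to 94.4 ± 9.06 CPM (log2 fold change -0.56, SE 0.111, edgeR adjusted p = 0.0172). Ido2 had a log2 fold change of -1.20 (SE 0.374, edgeR adjusted p = 0.0646) at 1.03 ± 0.318 against 0.447 ± 0.0678 CPM, and Ccbl1, or Kyat1, one of -0.45 (SE 0.198, edgeR adjusted p = 0.152). Afmid, Acmsd and Got2 had log2 fold changes of 0.71, 0.24 and -0.06 with edgeR adjusted p of 0.368, 0.619 and 0.83. Up to 44.2% of the exonic sequence of Afmid overlaps another gene on its strand. Adjusted over the list alone, 2 genes were lower and 0 higher. The main kynurenine-forming enzymes were close to undetected: Ido1 had 2, 0 and 1 counts in the control libraries and 1, 0 and 0 in the knockdown libraries, and Tdo2 had 1 count in control replicate 3 and 0 elsewhere. Kynu had 0 to 14 counts per library, and Kmo, Haao and Qprt had 0 in all 6, which allows up to 0.185 to 0.251 CPM depending on the library. The list as a whole did not pass the competitive test (median log2 fold change -0.26, camera adjusted p = 0.398). The call for Ccbl2 was lost without control replicate 3 or any 1 knockdown replicate, the highest adjusted p being 0.0894, and without control replicate 1 the list had 3 lower members, Ccbl2, Ido2 and Got2.

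Genes around that pathway moved in both directions. Of 12 measured genes of tryptophan transport, the serotonin branch and the aryl hydrocarbon receptor, 3 were higher and 2 lower, the same numbers as when adjusted over the list alone. Nqo1, a quinone reductase gene, rose from 1.43 ± 0.29 to 7.29 ± 0.706 CPM (log2 fold change 2.36, SE 0.224, edgeR adjusted p = 0.00288). The monoamine oxidase gene Maoa rose by 0.43 and the receptor's target Cyp1a1 by 0.70 on the log2 scale. Cyp1a1 fell outside the naming rule and was named after its values were seen. Ahrr, which encodes the receptor's repressor, fell by 1.63, and Tiparp, another target of the receptor, by 0.46. The list did not pass (camera adjusted p = 0.423). Its median was 0.16 over 12 genes, and -0.10 without control replicate 1, where 13 genes could be tested. Of Nqo1, Ahrr, Tiparp and Maoa only Nqo1 kept its call with each library left out.

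The title also names infiltration of CD8+ T cells, and the cells' own chemokine transcripts were examined for that reason. Of 24 chemokine genes, 12 could be tested, and 3 were higher and 1 lower. Cx3cl1, the membrane-bound chemokine fractalkine (chromosome 8, 94772009 to 94782423), rose from 14.5 ± 3.72 to 93.8 ± 4.8 CPM, 6.45-fold (log2 fold change 2.69, SE 0.197, edgeR adjusted p = 0.00153). Cxcl15 rose from 14.6 ± 3.92 to 40.9 ± 3.6 CPM (1.48, SE 0.211, edgeR adjusted p = 0.00681), and Ccl9 had 0 to 4 counts in control libraries against 26 to 40 in knockdown libraries (3.91, SE 0.662, edgeR adjusted p = 0.0108). Cxcl16 fell by 0.51 on the log2 scale (edgeR adjusted p = 0.0322), with up to 18.3% of its exonic sequence overlapping a gene on the opposite strand. Of the ligands of CXCR3, a chemokine receptor on T cells, Cxcl10 had a log2 fold change of -0.21 (SE 0.16, edgeR adjusted p = 0.394). Cxcl11 had 1 to 6 counts per library, and Cxcl9 had 1 count in knockdown replicate 3 and 0 elsewhere. Ccl2 and Cxcl5, with log2 fold changes of 1.04 and -1.76, had edgeR adjusted p of 0.145 and 0.0825. These 6, Ccl2, Cxcl5, Cxcl9, Cxcl10, Cxcl11 and Ccl5 (0 to 4 counts), lie outside the naming rule and were chosen after their values were seen. Adjusted over the list alone, 3 were higher and 3 lower. The list did not pass (camera adjusted p = 0.551), and its median of -0.17 was opposite in sign to its mean of 0.42 and to the upward direction of the test. Without control replicate 1, 5 were higher and 2 lower, and the median was 0.25. Cx3cl1 and Cxcl15 kept their calls with each library left out, while Ccl9 and Cxcl16 lost theirs in at least 1 such fit, with highest adjusted p of 0.0603 and 0.126.

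**Figure D2:**
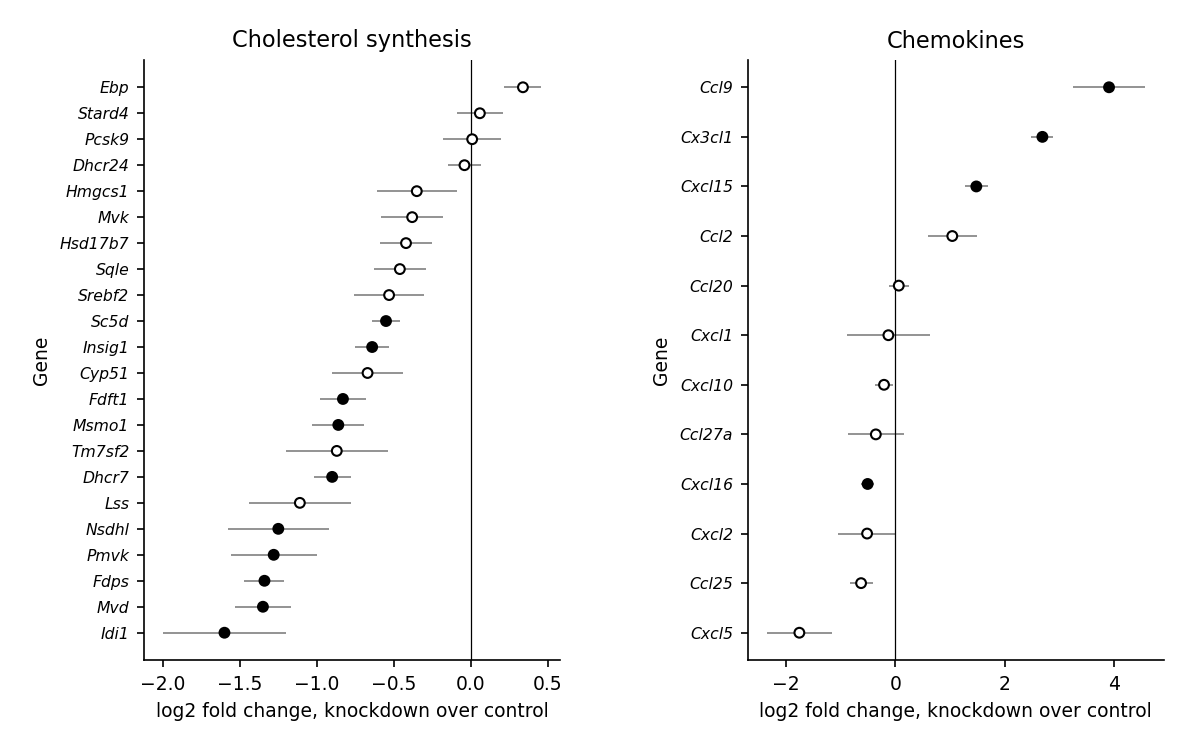
Log2 fold change, knockdown over control, of 22 of the 24 measured members of the cholesterol synthesis list (left, without 2 that did not pass) and each of the chemokine list (right). Points are edgeR estimates from 3 libraries per group, lines are ± 1 SE, and filled points have an adjusted p below 0.05 over all genes tested. In the cholesterol list 10 members are filled, all of them below 0, and in the chemokine list Ccl9, Cx3cl1 and Cxcl15 lie above 0 and Cxcl16 below.

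Genes of antigen presentation and immune regulation changed at some members of each list, and none of these lists passed. Of 20 genes of MHC class I presentation, 4 were higher and 0 lower, as also when adjusted over the list alone. These were the peptidase gene Erap1 (log2 fold change 0.87), the peptide transporter gene Tap1 (0.77), the transactivator gene Nlrc5 (0.84) and H2-M3 (0.76), whose reads could be shared with related class I genes, with camera adjusted p = 0.386. Of 12 checkpoint ligands and immunosuppressive factors, 2 were higher and 1 lower, the same numbers as when adjusted over the list alone. Pdcd1lg2, the gene of PD-L2, rose by 0.77, the nectin family ligand gene Pvr rose by 0.53, and Vegfa fell by 0.38 on the log2 scale (camera adjusted p = 0.423). Of 24 interferon response genes, 4 were higher and 3 lower, again unchanged when adjusted over the list alone. Cmpk2 rose by 1.56 and Irf1 by 0.64, while Stat2 and Bst2 had log2 fold changes of -1.19 and -0.90 (camera adjusted p = 0.939, with a list median of -0.14 and a mean of 0.02). Of 14 NF-kappaB and inflammatory genes, 2 were higher and 0 lower, adjusted either way, namely Il6ra (1.70) and Nfkbia (0.73), with camera adjusted p = 0.171. Cmpk2, Stat2, Il6ra and Nfkbia kept their calls with each library left out, and the other genes of this paragraph lost theirs in at least 1 such fit, with adjusted p of up to 0.153. Without control replicate 1 the higher and lower members numbered 8 and 4 for MHC class I, 5 and 2 for checkpoint, 4 and 6 for interferon and 5 and 3 for NF-kappaB genes. The NF-kappaB median went from 0.23 over 14 genes to 0.04 over the 15 that could then be tested. In that fit 6313 of all 12108 genes tested passed, against 2466 of 11975 with all libraries, so the rise in calls is not particular to these lists.

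Cholesterol synthesis was the only one of the 23 lists tested that passed the threshold. Of its 24 genes, 0 were higher and 10 lower, or 12 lower when adjusted over the list alone, with a median log2 fold change of -0.60 (camera adjusted p = 0.00212 with a preset correlation). The call was not kept with an estimated correlation (0.635), where the list had a camera adjusted p = 0.828 and no list passed. Without control replicate 1 the estimated correlation was -0.0408, below the preset value, yet the camera adjusted p was 0.239. Correlation therefore does not account for the loss in that fit. Fdps, the farnesyl diphosphate synthase gene, fell from 213 ± 34.7 to 84.3 ± 2.6 CPM (log2 fold change -1.34, SE 0.135, edgeR adjusted p = 0.00324). Up to 26.7% of its exonic sequence overlaps another gene on its strand. Mvd, the mevalonate decarboxylase gene, fell by 1.35 and Dhcr7, the last reductase of the pathway, by 0.90, and these 3 kept their calls with each library left out. Sc5d, a sterol desaturase gene, fell by 0.55 and lost its call in 3 of the 6 such fits. The other 14 genes of the list did not pass. The list was also low in control replicate 1, where its median lay 0.54 below control replicates 2 and 3 on the log2 scale, against 0.72 below them in the knockdown libraries, whose mitochondrial share of 5.6% to 6% lay between those of the controls.

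Of the other lists of metabolism and stress, none passed, and most of their calls were falls except in amino acid metabolism. In the unfolded protein and integrated stress response, 1 of 25 genes was higher and 8 were lower, or 2 and 8 when adjusted over the list alone (median log2 fold change -0.43, camera adjusted p = 0.109). Ddit3, the gene of the stress factor CHOP, fell from 298 ± 41 to 98.6 ± 3.85 CPM (-1.60, SE 0.124, edgeR adjusted p = 0.00174), and Creld2, Hsp90b1 and Atf4 fell by 1.13, 0.51 and 0.46 on the log2 scale. Of 22 genes of fatty acid synthesis and oxidation, 0 were higher and 5 lower, adjusted either way, among them the lipid droplet gene Plin2 (-0.83), the elongase gene Elovl6 (-0.84), Dgat2 (-1.05) and Acacb (-1.15), with camera adjusted p = 0.398. Of 18 glycolysis genes, 1 was higher, Pfkfb3 (0.65), and 2 were lower, Aldoa (-0.87) and Pfkl (-0.82), with none passing when adjusted over the list alone and camera adjusted p = 0.248. Of 22 genes of amino acid, serine and glutathione metabolism, 5 were higher and 2 lower, or 6 and 2 when adjusted over the list alone. They included Gclc (0.59), Shmt1 (0.35), Cth (-0.69) and Srm (-0.45), with camera adjusted p = 0.171. Without control replicate 1, whose mitochondrial share was 10.51%, these 4 lists passed, with camera adjusted p of 0.00116, 0.0431, 0.000867 and 0.0431 in the order given, and higher and lower members numbered 3 and 16, 2 and 12, 1 and 12, and 11 and 2. In that fit none was kept with an estimated correlation (adjusted p = 0.407, 0.346, 0.346 and 0.346). Ddit3 and Plin2 kept their calls with each library left out, and the other genes named here lost theirs in at least 1 such fit, with adjusted p of up to 0.167.

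**Figure D3:**
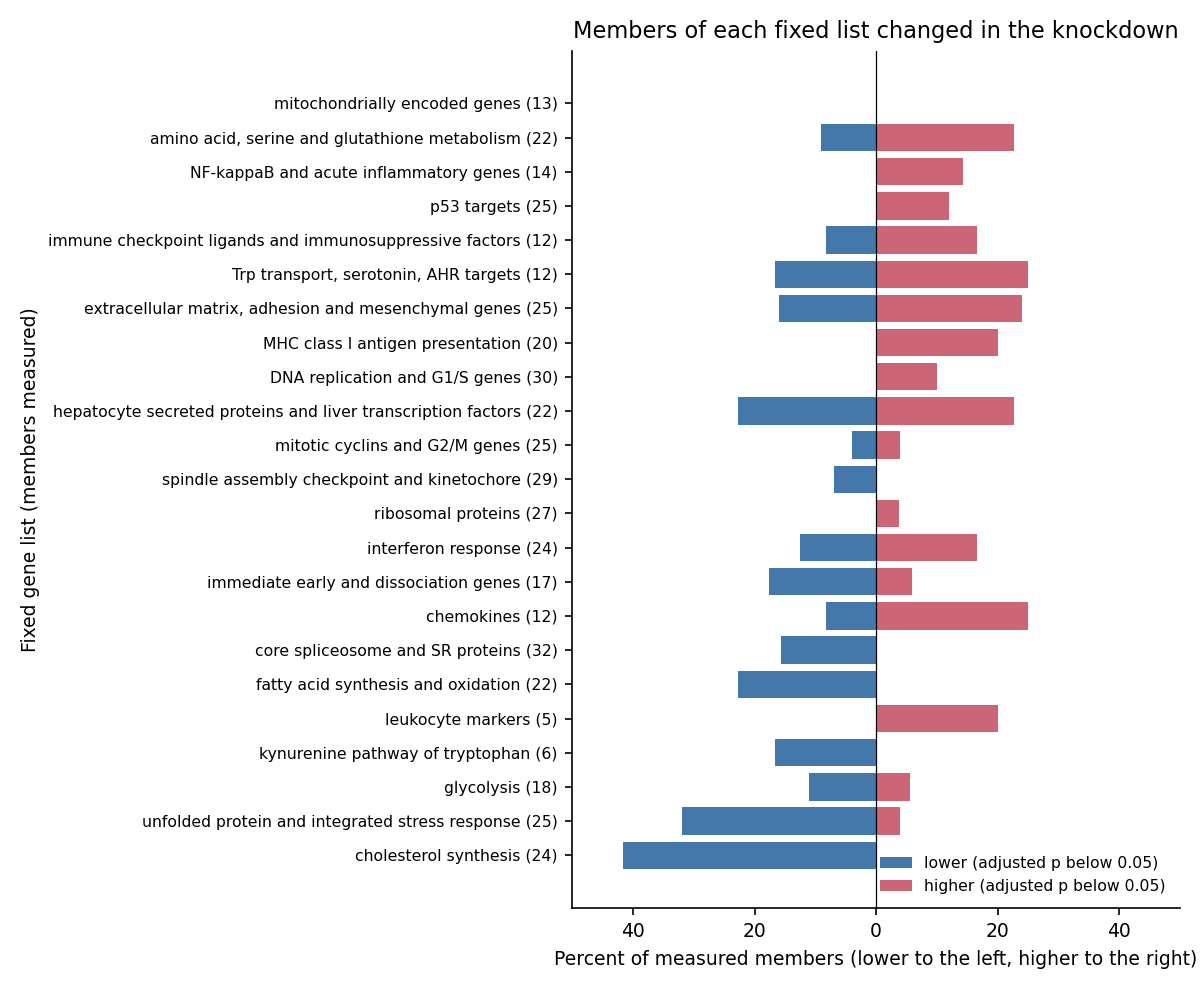
Percent of the measured members of each fixed gene list that were lower (blue, to the left) or higher (red, to the right) in knockdown cells at an edgeR adjusted p below 0.05, for the 23 lists with at least 5 measured members, ordered by median log2 fold change with the number measured in brackets. The largest share of lower members is in the cholesterol synthesis list, 10 of 24, and the stress response list follows with 8 of 25.

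Cell division genes, the setting in which BuGZ is best known, changed at few members when all libraries entered. Of 29 spindle checkpoint and kinetochore genes, 0 were higher and 2 lower, adjusted either way. Bub3, whose product binds BuGZ, fell from 245.2 ± 13.6 to 180.1 ± 2.14 CPM (log2 fold change -0.45, SE 0.085, edgeR adjusted p = 0.0151), and the kinetochore gene Ndc80 fell by 0.68 (camera adjusted p = 0.824). Of 25 G2/M genes, Ccna2 was higher (0.61) and Nusap1 lower (-0.46), adjusted either way, with camera adjusted p = 0.462. Of 30 replication and G1/S genes, 3 were higher and 0 lower, adjusted either way: E2f2 (1.52), Mcm5 (0.66) and Rfc3 (0.68), with camera adjusted p = 0.423. Of 25 p53 targets, 3 were higher and 0 lower, adjusted either way: Btg2 (0.55), Eda2r (0.81) and Tnfrsf10b (0.40), with camera adjusted p = 0.171. Of 32 spliceosome and SR protein genes, 0 were higher and 5 lower, or 4 lower when adjusted over the list alone, including Snrnp70 (-0.57), Snrpa (-0.55), Srsf3 (-0.52) and Snrpd3 (-0.49), with camera adjusted p = 0.239. Ndc80 and E2f2 kept their calls with each library left out, and the other genes named here lost theirs in at least 1 such fit, with adjusted p of up to 0.145. Without control replicate 1 the higher and lower members numbered 7 and 7 for the spindle list, 5 and 6 for G2/M, 11 and 4 for replication, 12 and 4 for p53 targets and 5 and 16 for the spliceosome. Calls rose among all genes too, to 6313 of 12108 from 2466 of 11975, so the rise is not particular to these lists.

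Liver and matrix genes changed in both directions. Of 22 measured hepatocyte genes, 5 were higher and 5 lower, or 7 and 6 when adjusted over the list alone. The fetal liver protein gene Afp rose from 867.5 ± 117 to 1889 ± 105 CPM (log2 fold change 1.12, SE 0.138, edgeR adjusted p = 0.0048), while Ass1, a urea cycle enzyme gene, Nr1h4, the gene of the bile acid receptor FXR, and Apoe fell, with log2 fold changes of -1.94, -1.19 and -0.65. That list had a median of 0.06 and a mean of -0.01 (camera adjusted p = 0.678). Of 25 genes of matrix, adhesion and mesenchymal state, 6 were higher and 4 lower, or 6 and 5 when adjusted over the list alone, with camera adjusted p = 0.398. Tgfbi was among the higher genes, whereas the osteopontin gene Spp1 fell by 1.13 and the epithelial adhesion gene Epcam by 1.54. For Spp1, up to 18.8% of the exonic sequence overlaps another gene on its strand. The higher and lower members numbered 9 and 5 of 23 hepatocyte genes and 9 and 8 of 25 matrix genes without control replicate 1. In that fit 6313 of all 12108 genes tested passed. All of the genes named here except Apoe, whose highest adjusted p was 0.0856, kept their calls with each library left out.

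Lists that track RNA quality, handling and other cell types gave few calls when all libraries entered. None of the 13 mitochondrially encoded genes passed with all libraries, at a median log2 fold change of 0.30 (camera adjusted p = 0.34). Without control replicate 1, 12 were higher, with a median of 1.52 (camera adjusted p = 2.33e-06, or adjusted p = 0.459 with an estimated correlation). Among them mt-Co1 had a log2 fold change of 0.40 that became 1.72, and mt-Atp6 one of -0.16 that turned to 0.31. Of 27 ribosomal protein genes, 1 was higher, Rps2 (0.51), which has many pseudogene copies, and none adjusted over the list alone (camera adjusted p = 0.824). In the fit without control replicate 1, 16 ribosomal genes were higher and 5 lower, and the median went from -0.06 to 0.33 (camera adjusted p = 0.0513). Of 17 immediate early genes, 1 was higher, Dnajb1 (0.52), and 3 were lower, Fosb (-1.63), Jund (-1.58) and Fos (-0.50), adjusted either way, with camera adjusted p = 0.534. For Jund, up to 52.6% of the exonic sequence overlaps a gene on the opposite strand. Neither of the 2 measured histone genes, Hist1h1c (0.16) and Hist1h2bc (-1.24), passed. With control replicate 1 left out Hist1h1c was higher (0.72, edgeR adjusted p = 0.00238), Hist1h2bc had a log2 fold change of 0.14, and the immediate early list had 3 higher and 6 lower members. Of 20 leukocyte markers 5 could be tested and Csf1r was higher, at 0.479 ± 0.352 against 3.24 ± 0.155 CPM (2.68, SE 0.468, edgeR adjusted p = 0.0117), with up to 15.1% of its exonic sequence overlapping a gene on the opposite strand. That list had a median of -0.26, a mean of 0.40 and an upward direction with camera adjusted p = 0.824. The 3 measured endothelial markers, among them Esam (0.21) and Pecam1 (0.68), did not pass. Of the 4 measured fibroblast and stellate cell markers Rgs5 was higher (1.81) and Pdgfra lower (-0.54), or 2 higher and 1 lower when adjusted over the list alone. None of the 6 erythroid markers could be tested. In this paragraph only Fosb kept its call with each library left out.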

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

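The covariate, left-out mitochondrial genes length and GC offsets and an estimated correlation in 5 libraries were chosen after seeing the data. Zfp207 kept its direction and call under every alternative run, between -2.11 and -1.82 with each library left out. With each library left out in turn the count of changed genes ranged from 534 to 6313, the count at least 2-fold from 323 to 1092, the number of lists past the threshold from 1 to 6, the kynurenine list median from -0.36 to -0.16 and the chemokine list median from -0.38 to 0.25. The number of libraries alone does not order these counts, since the fit without control replicate 1 gave the most: the common biological coefficient of variation was 0.2 with all libraries and 0.094 without it. The mitochondrial share covariate gave 6433 genes, 1107 of them at least 2-fold, and an adjusted p below 0.01 left 707 and 348. On FPKM the 2-fold count was 223 with log2(FPKM + 1), 405 with log2(FPKM + 0.1) and 212 without a filter, where the added constant shrinks the folds of low genes. The other alternatives, the replicate block apart, gave 2009 to 3064 genes, none of those shared with the 2466 having the opposite sign. Upper-quartile scaling shifted the median of all genes to -0.088 and made 39.1% of calls higher, against 48.2%. Lists past the threshold numbered 2 with no low count filter, with DESeq2, with log2(FPKM + 1) without a filter and with length and GC offsets, 0 with an estimated correlation, whether in all libraries or in the 5 other than control replicate 1, and 5 with fry. With fry, which asks a different question, the spliceosome list passed downward (fry adjusted p = 0.0114). The p53, amino acid and MHC class I lists passed upward (fry adjusted p = 0.0132, 0.0232 and 0.032). The kynurenine list, at a median of -0.26, also passed downward (fry adjusted p = 0.032). Its camera adjusted p lay between 0.282 and 0.506 with each library left out and was 0.828 with an estimated correlation. With log2(FPKM + 1) or log2(FPKM + 0.1) and a mean FPKM of at least 1, too few of its members remained for a list test. The cholesterol list kept its call in 19 of 22 alternatives, with medians from -0.72 to -0.48, and lost it with an estimated correlation (adjusted p = 0.828, or 0.239 in those 5 libraries) and fry (adjusted p = 0.0832). The only named gene to change direction with a call was mt-Atp6, from -0.16 to 0.31 without control replicate 1 (adjusted p = 0.00664). For other named genes, 85 gene-by-setting calls were lost and 4 gained outside the left-out libraries, and 204 lost and 4 gained within them. The cause was not tested. A replicate block gave 987 genes. The labels do not say that equal numbers mark a shared day or culture, so the numbers were not taken to pair the samples. Deviations of same-numbered libraries from their group means correlated at -0.008, 0.008 and 0.053, all under 0.1. Control replicates 1 and 2 did not correlate best with their own number, while control replicate 3 did. These correlations do not exclude a pairing. Depth limits genes near the 3-count ceiling of 0.185 to 0.251 CPM, such as Ido1, Tdo2 and Kmo, where no change was detectable at this depth.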

Other observations

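Further genes outside the naming rule changed, and the genes of this paragraph were chosen after their values were seen. Ephx1, the microsomal epoxide hydrolase gene, went from 64.3 ± 10.9 to 235.7 ± 4.01 CPM (log2 fold change 1.88, SE 0.134, edgeR adjusted p = 0.00153), and the carboxylesterase gene Ces2e from 11.9 ± 6.25 to 54.3 ± 1.78 CPM (2.20, SE 0.336, edgeR adjusted p = 0.00816). Gsta3, a glutathione transferase gene, had a log2 fold change of 2.93 and the metallothionein gene Mt2 one of -1.90, beside -1.75 for Mt1. Thbs1, the thrombospondin gene of the matrix list, rose by 2.15 and the albumin gene Alb by 1.29 on the log2 scale. Decorin, Dcn, usually a fibroblast product, was abundant in both groups at 2178 ± 159 and 2729 ± 56.7 CPM (0.33, edgeR adjusted p = 0.0968). The summed CPM of the lists of other cell types, for which no test was made, was 37.6 to 43 in control and 44.7 to 45.7 in knockdown libraries for leukocyte markers, 44.7 to 48.7 and 49.4 to 56.5 for endothelial markers, 2047.3 to 2310.6 and 2704.5 to 2787.2 for fibroblast and stellate cell markers, and 0.1 to 0.2 and 0.5 to 0.8 for erythroid markers. Few genes carry these sums, with Dcn nearly all of the fibroblast sum and Esam (adjusted p = 0.164) nearly all of the endothelial sum. Of the markers 16 of 21, 9 of 12, 8 of 12 and 6 of 6 were under 1 CPM in every library, in the same order of leukocyte, endothelial, fibroblast and erythroid lists. The 20 symbols of the leukocyte list correspond to 21 gene identifiers in the deposited data.

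The tests that were chosen after their results were seen are the label check, the chi-square test, the test of a shared library property, the rule for genes near 0 in 1 library and the adjustment over the 2 lists of the last paragraph. Of the 10 splits of the 6 libraries into 3 and 3, the real split gave 2466 genes and 702 at least 2-fold, and the highest other split gave 0 and 0, so that 1 of 10 was as large. For lists, 7 of 10 splits gave as many as the real 1, the highest other being 7. The kynurenine list had as small a camera p in 3 of 10 of these permutations (real 0.198, smallest other 0.13) and the chemokine list in 8 of 10 (real 0.431, smallest other 0.0316). With 10 splits no share can fall under 0.05. The splits with 6 or 7 lists are those that put control replicate 1 with 2 knockdown libraries, which points to a structure of the samples.

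Control replicate 1 stands apart from the other controls, and lower depth, a knockdown library under a control label and a length and GC trend were weighed. With the other 2 controls thinned to its total, chi-square per degree of freedom was 19 times as large against it as between them, which counting noise cannot give, and the SD of log2 ratios between them was 0.48 of that against it (SE 0.013). Its Zfp207 level was 2.94 times the highest knockdown library, and length and GC explained 8.6% (SE 0.53) of its difference over genes, so neither is the whole source. By length, its median log2 difference from the other controls was 0.28 in the shortest quintile of genes and -0.28 in the longest. The knockdown libraries had 0.01 and 0.03 there. At 10 genes control replicate 1 had under 1/8 of the lowest other library, where the other libraries had 0 or 1 such genes. Sp1 had 52 counts against 2781 to 3379, Zfp292 12 against 1414 to 1675 and Pou2f1 25 against 1515 to 1732, with no overlapping gene on their strand. A difference in RNA or library preparation, in culture or in the authors' counting may be the source and was not tested.

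The knockdown libraries differ from control replicates 2 and 3 partly in the direction of control replicate 1. Over genes, the difference of control replicate 1 from control replicate 3 and that of the knockdown mean from control replicate 2 had a Spearman rho of 0.24, and 0.204 with the baselines exchanged, where genes are not independent replicates. Without mitochondrial genes rho was 0.241, but leaving them out rescales each library by 1 factor and cannot alter ranks over genes, so that this test says nothing about them. The 2 baselines, control replicates 2 and 3, correlated with each other at r = 0.989. A departure shared by these libraries alone would also give a positive rho and cannot be told apart here. A library property shared with control replicate 1, seen in mitochondrial share and Malat1, is a candidate explanation that the positive rho goes with. An effect of the knockdown on the same genes stays open and untested.

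The cholesterol synthesis list may be lower through the knockdown or through that shared property. With length and GC offsets its median was -0.61, which argues against such a trend. With the mitochondrial share as a covariate it was -0.48, but the bound set in advance, -0.3, was a poor one: the covariate rests mostly on control replicate 1, and 22 of the 24 genes were also below control replicates 2 and 3 in that library, with a median of -0.54. A camera p as small as the real 9.21e-05 came from 4 of 10 splits, the smallest other being 5.66e-08, with control replicate 1 beside 2 knockdown libraries. The explanations cannot be told apart for this list with 1 such control library.

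Because Nqo1, Gsta3, Ephx1, Ces2e and Ces2g rose, a broader rise of antioxidant or of drug-metabolising genes was taken as a hypothesis and tested on lists that leave these genes out. The antioxidant and phase II list had 28 measured genes, 1 higher and 4 lower, with a median log2 fold change of -0.06 (SE 0.1) and camera adjusted p = 0.649 over these 2 lists. The drug-metabolising and bile transport list had 10, 1 higher and 2 lower, with a median of -0.15 (SE 0.37) and the same adjusted p. Abcb4 and Slco1a4, transporter genes among the largest rises, were not among these 10 either, so the result does not cover them. The antioxidant list also left out the genes of the fixed lists, so its result does not cover those. Among them was Gclc (log2 fold change 0.59), from the amino acid, serine and glutathione list. In that list 5 of 22 genes were higher and 2 lower. Neither test showed a broader rise, and members going both ways around 0 do not exclude one in part of each list.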
